A study of Rattus norvegicus with 36 samples.

How the data were processed

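Total RNA from whole rat lung was hybridised as biotin-labelled cRNA to 36 one-colour Illumina beadchip arrays. Per the labels' protocols, the RNA was extracted with Trizol, treated with DNase and amplified with the Ambion MessageAmp kit. The labels give 3 strains (Lewis, Fisher and Brown Norway) and postnatal days 1, 7 and 14, written here as PN1, PN7 and PN14. Each strain and age had 4 arrays, apart from Lewis PN1 with 3 and Brown Norway PN1 with 5. Groups, replicate numbers, slides and positions were taken from the labels alone.

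The deposited scanner table holds, per the file headers, a raw signal (probe intensity on a linear scale), a detection p-value and a bead count for each of 22226 probes on each array. The deposited signal was not normalised, and no value of it is at or below 0. How the deposited detection p-values were computed is not given in the sources used here. The number of beads behind each deposited intensity was empty in 5096 cells of 280 probes. The authors also deposited log2 values of the same arrays, processed with lumi per the submitters' processing notes, without a version or settings. Those log2 values have the same quantiles on every array, with a median of 5.85 on each, and rank exactly as the raw signal of their own array. They are not centred by gene and their background was lowered before the log, but the method for the background is not given in the sources used here. The deposited scanner table also holds 36 per-sample columns of another measure, which were not used.

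The arrays detected between 9451 and 10583 probes at a detection p under 0.01, with a median of 9977. The median raw signal per array lay between 212.76 and 294.89, and the median number of beads per probe between 40 and 43. The precision of each comparison is limited by the number of arrays in a group.

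Raw intensities were background-corrected with normexp, using the detection p-values and an offset of 16, then quantile normalised and log2 transformed with the neqc function of limma 3.58.1 in R 4.3.3. Tables were read with version 1.17.8 of data.table, and figures were drawn with matplotlib 3.10.9. Probes with a detection p under 0.01 on at least 3 arrays were tested, which kept 11339 probes and removed 10887. Gene symbols came from GEO's platform annotation of the array, which can be old. It gave 1 gene for 13192 probes and several for 0. The other 9034 probes are unnamed here. Of the named probes, 13151 were matched to a current rat gene table through their gene identifier, and 0 symbols had to be updated. The tested probes included 8115 named ones for 8063 genes.

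A linear model with 1 mean per strain and age was fitted to all 36 arrays with limma, so that all groups shared an estimate of the spread, with 28.6 degrees of freedom after moderation. Strain contrasts were averaged over the 3 ages, and age contrasts over the 3 strains. Each strain contrast was also tested at each age. The difference between strains in the change from PN1 to PN14 was tested pairwise, and a moderated F test covered all strain by age terms. P-values are 2-sided and adjusted by Benjamini-Hochberg over the tested probes, with a threshold of 0.05. A probe counted as apart in Brown Norway when it passed against both other strains with the same sign. Folds are 2 to the power of the absolute log2 difference. Where a probe was not detected on any array of the dimmer side, the fold is given as "at least" a bound. The bound sets the bright group's mean against the dim side's mean of, per array, the higher of the lowest signal among detected probes and the probe's own signal. Background correction with an offset shrinks the folds of dim probes.

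Gene lists for pathways, cell types, tissue carried over from outside the lung and sample handling were written before the data were examined, as were the groups, the tests, the rule for named genes and the first set of alternative settings. A list was tested where at least 4 of its genes were measured, with the probe of highest mean standing for each gene. The camera test of limma was used with a preset correlation of 0.01 and again with the correlation estimated from the data, adjusted over the lists of each contrast. The oesophagus list had 2 measured genes and was only described, and the male-specific and female-specific lists had 0 named probes on the array.

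Genes named below had to pass the threshold, carry 1 symbol that is not a placeholder, and be detected on every array of at least 1 group. For Brown Norway, the rule took the 12 highest and the 12 lowest by the smaller of both differences, with the same sign at each age. It took 8 in each direction between Lewis and Fisher and 10 in each direction for each step in age, with the same sign in each strain. It also took the 10 smallest interaction p-values and up to 4 passing members of each list. Il4, Il13, Il33, Acta2, Myh11, Eln, Col1a1, Dcn, Sftpc, Scgb1a1, Mki67 and Hbb were given whatever their values.

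The labels place the arrays on 3 slides of 12. Each age has its own slide apart from 3 arrays: Lewis PN7 replicate 1 lies on the slide of PN1, Lewis PN14 replicate 1 on that of PN7, and Brown Norway PN1 replicate 5 on that of PN14. Each slide holds 4 Fisher arrays, and 4 Lewis and 4 Brown Norway arrays on the slides of PN1 and PN7 against 3 and 5 on that of PN14. Apart from those 3 arrays, which share the last section of their slides, each strain keeps its own positions. Alternatives were no background correction, the authors' deposited log2 values, median scaling, other probe filters, the slide as a fixed or random block, comparisons within a slide, replicate number as a block, a trended and robust variance, and leaving out each array in turn. A sex covariate was not used here because the array had 0 named Y-linked probes. Analyses without 2 Brown Norway arrays that resemble each other's group, with heart and adipose signal as covariates, and without the 3 arrays with most skeletal muscle signal were chosen after seeing the data.

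The fitting steps were tested on simulated data for all 11339 probes. For Brown Norway minus Fisher, the fit recovered 66 of 67 probes changed 1.5-fold, 67 of 67 changed 2-fold and 66 of 66 changed 3-fold, with 17 false calls among 216. At PN1 alone it recovered 63 of 67, 67 of 67 and 65 of 66, with 9 false calls among 204. For PN7 minus PN1 it recovered 66 of 67, 67 of 67 and 66 of 66, with 17 false calls among 216. Simulated data without an interaction gave 0 interaction calls. For the strain by age results, residuals of the fit without the tested term were also reordered over the arrays, in 100 orders with the real one, and limma's fit was repeated, a test chosen after seeing the data. A simulated list shifted by 0.5 log2 in Brown Norway minus Fisher had an adjusted p of 2.64e-92, and 0 other lists were called. The simulated genes varied independently, while the correlation estimated within the real lists reached 0.851, for skeletal muscle genes. That simulation therefore does not show how the list test behaves with correlated genes.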

Results

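The series addressed how inherited differences between rat strains shape gene expression in the developing lung, as a background to asthma susceptibility. Whole-lung RNA was profiled on 36 arrays from Lewis, Fisher and Brown Norway rats at PN1, PN7 and PN14, with 3 arrays for Lewis PN1, 5 for Brown Norway PN1 and 4 for each other group. Brown Norway rats are widely used as a model of allergic airway inflammation. The labels do not state that replicates came from separate animals, so p-values measure only the spread between these samples, which may be technical. The correlation between replicates over the tested probes ranged from 0.995 to 0.998 in Lewis PN1, from 0.964 to 0.992 in Brown Norway PN1 and from 0.971 to 0.996 in Brown Norway PN14.

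The first principal component held 26.3% of the variance and, apart from the 2 arrays named next, separated PN14 from the earlier ages, while PN1 and PN7 overlapped (Brown Norway PN1 replicate 1 at -8 and PN7 replicate 2 at -9.9). The second held 21.7% and separated Brown Norway PN1 from the other groups. The arrays labelled Brown Norway PN1 replicate 5 and Brown Norway PN14 replicate 3 each lay among the arrays of the other's group. Replicate 5 correlated at 0.997 with the mean of Brown Norway PN14 and at 0.974 with that of its own group. Replicate 3 correlated at 0.994 with the mean of Brown Norway PN1 and at 0.975 with that of its own group. The other 34 arrays were nearest to their own group, and both arrays were kept under their labels. Each age was hybridised almost wholly on a slide of its own, so every age contrast is also largely a contrast between slides.

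**Figure D1:**
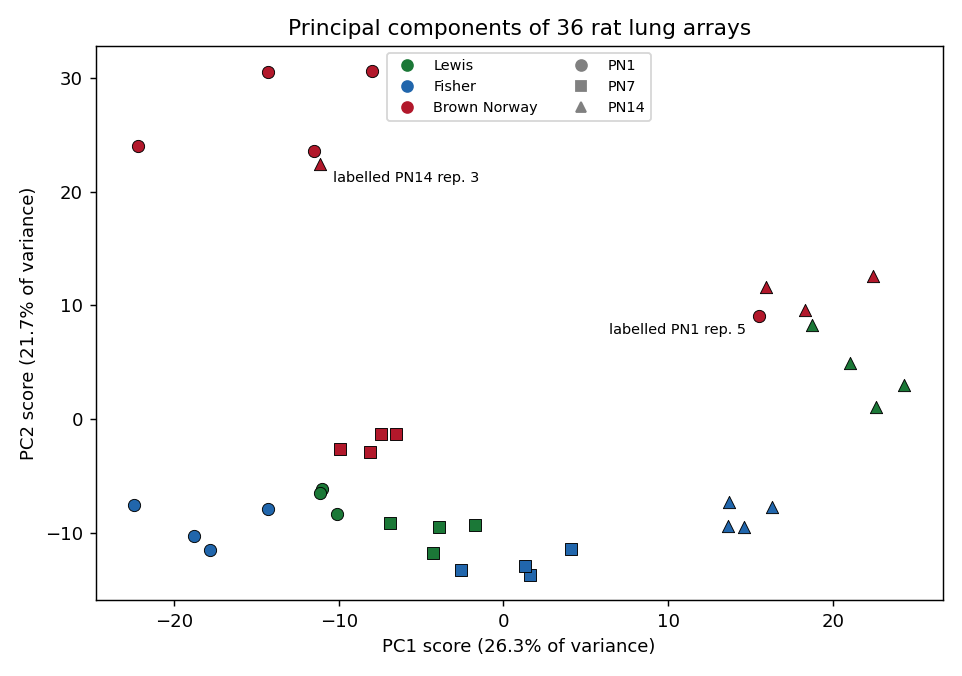
Scores of the 36 arrays on the first (x axis, 26.3% of variance) and second (y axis, 21.7%) principal component, coloured by strain and shaped by age. The array labelled Brown Norway PN14 replicate 3 lies beside the Brown Norway PN1 arrays, and that labelled Brown Norway PN1 replicate 5 beside the PN14 arrays.

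Among the genes furthest above both other strains in Brown Norway lungs, with the same sign at every age, were Cavin2 and 3 class I histocompatibility genes. Cavin2, a structural protein of caveolae, was 8.92-fold higher than in Fisher (log2 3.16, SE 0.08) and 8.13-fold higher than in Lewis. The class I histocompatibility genes RT1-CE16 and RT1-A1 were 7.73-fold and 3.72-fold higher than in Fisher, and 9.02-fold and 4.32-fold higher than in Lewis. RT1-A2, of the same family, was at least 5.05-fold higher than in Fisher, where it was detected on 0 arrays, and 5.04-fold higher than in Lewis, where 3 arrays of PN14 detected it. Nfib, a transcription factor needed for lung maturation, was 5.42-fold higher than in Fisher and 4.75-fold higher than in Lewis. The limma adjusted p for these genes ranged from 2.35e-26 for RT1-CE16 against Lewis to 1.12e-12 for RT1-A2 against Lewis. A probe can also read lower where a strain's sequence differs under it. The strains' sequences were not compared here for these genes or for those below.

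Further genes higher in Brown Norway were Ly6i, a surface protein of the Ly6 family, 5.93-fold against Fisher and 4.39-fold against Lewis, and the peroxisomal membrane gene Pxmp4, at least 3.89-fold against Fisher and 3.93-fold against Lewis. Ankra2 was at least 3.69-fold and 3.81-fold higher. The mRNA export gene Rae1, the complex I assembly gene Ndufaf5, the vesicle transport gene Tmed5 and the tRNA methyltransferase gene Trmt13 were 3.07-fold, 3.03-fold, 2.81-fold and 2.68-fold higher than in Fisher.

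Genes lower in Brown Norway were led by Echdc2, 6.18-fold below Fisher (log2 -2.63, SE 0.04, adjusted p = 1.05e-29) and 6.34-fold below Lewis. Its Brown Norway signal lay at background, detected on 1 of 5 arrays at PN1 and on 0 at PN7 and PN14, so that the size of its fold depends on the background correction, and in the deposited values the log2 difference from Fisher was -5.81. Itga4, the integrin chain that guides leukocytes out of vessels, was 5.52-fold lower than in Fisher and 5.25-fold lower than in Lewis. Ly6c, a marker of monocytes, was 3.04-fold and 3.24-fold lower, and the complement protease gene C1s 2.82-fold and 2.17-fold lower. Kit, the receptor for stem cell factor on mast cells, was 1.98-fold lower than in Fisher (adjusted p = 2.55e-11) and 1.94-fold lower than in Lewis. The interferon-induced genes Ifi44 and Ifi47 were 3.4-fold and at least 2.16-fold lower than in Fisher, and 1.94-fold and at least 2.01-fold lower than in Lewis. Pyroxd2, the telomere helicase gene Rtel1, Pim3, Gchfr and Gata5 were 2.68-fold, 2.52-fold, 2.26-fold, 2.11-fold and 2.09-fold lower than in Fisher, and also passed against Lewis. The dim side was also near background for RT1-CE16, RT1-A2, Pxmp4 and Ankra2, which stood 6.34, 5.36, 5.01 and 5.41 above Lewis in the deposited log2 values, and for Ifi47, at -4.9 against Fisher. RT1 and Ly6 genes belong to families of closely similar copies, and a probe for such a gene can also read its relatives.

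**Figure D2:**
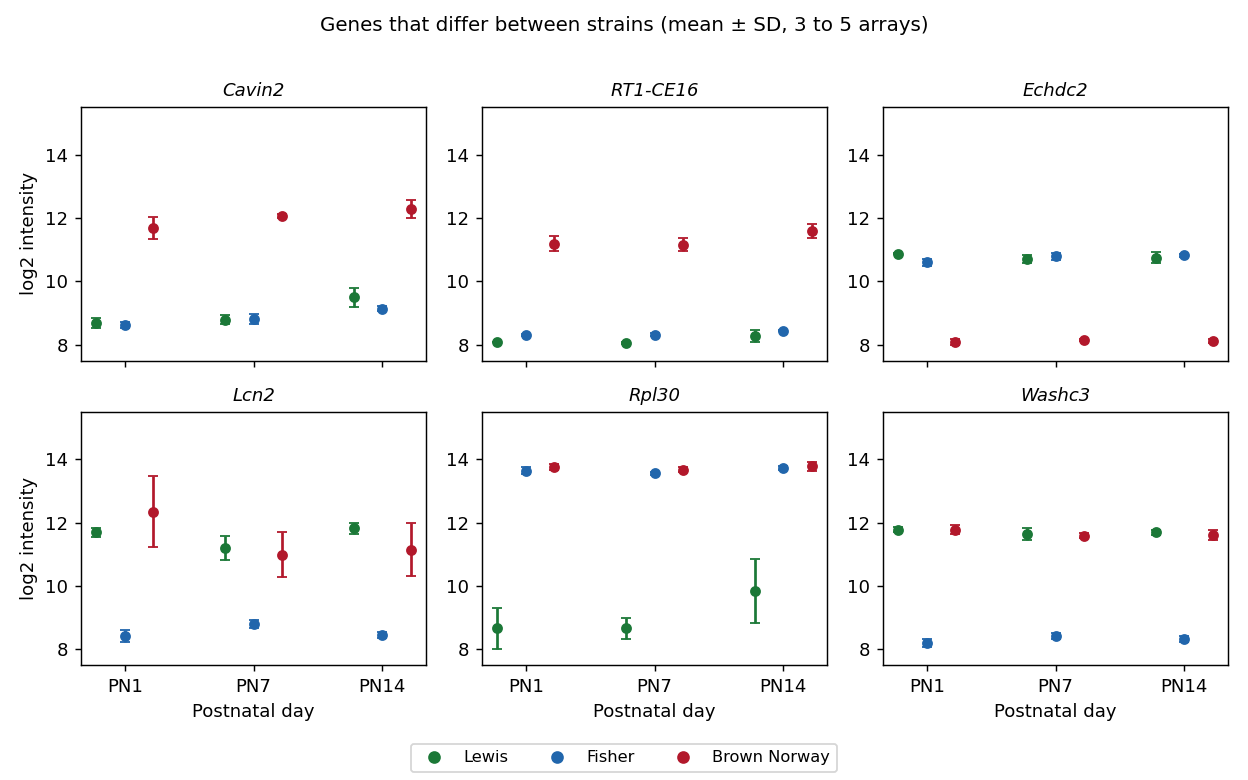
Log2 intensity (y axis, mean ± SD of 3 to 5 arrays) by postnatal day (x axis) for 6 genes that differ between strains. Cavin2 and RT1-CE16 are high and Echdc2 low in Brown Norway, Lcn2 and Washc3 are low in Fisher, and Rpl30 is low in Lewis at each age.

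Averaged over the ages, 3612 of 11339 probes differed between Brown Norway and Fisher (1573 higher and 2039 lower in Brown Norway), and 3157 between Brown Norway and Lewis (1432 higher and 1725 lower). At least 2-fold, 72 were higher and 37 lower in Brown Norway than in Fisher, and 55 were higher and 36 lower than in Lewis. In the same direction against both strains were 1860 probes, 838 higher and 1022 lower, and 45 of them were at least 2-fold apart from both, 31 higher and 14 lower. Independent lists of these sizes would share 198.7 higher and 310.2 lower probes. Unchanged groups simulated with the same shared Brown Norway arrays shared 0. The first of these values leaves out the shared arrays and the second leaves out the effects. The covariance of both sets of differences was 0.0352, against 0.00205 in the simulation. With the Brown Norway arrays divided between both comparisons, 1211 probes (556 higher, 655 lower) and 1182 probes (557 higher, 625 lower) were shared, against 120.7 and 176.3, and 122.6 and 177.9, for independent lists. Median scaling gave 1850 probes against Fisher (880 higher, 970 lower), 2440 against Lewis (1927 higher, 513 lower) and 870 apart from both (573 higher, 297 lower). With slide as a block, 3930, 3588 and 2177 probes passed.

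Of the 33 gene lists tested, 8 differed between Brown Norway and Fisher and 1 between Brown Norway and Lewis. With the correlation within each list estimated from the data, 0 of the 33 passed limma's camera test in either contrast, and 1 and 0 had an unadjusted p under 0.05. Class I presentation genes were higher in Brown Norway than in Fisher, 10 of 16 higher and 2 lower, or 10 and 3 adjusted over the list alone (median log2 0.37, adjusted p = 0.000292; adjusted p = 0.954 with an estimated correlation). Against Lewis 9 were higher and 2 lower, with the same counts adjusted over the list alone (adjusted p = 5.25e-05; adjusted p = 0.995 with an estimated correlation). Immediate early genes, which respond to handling as well as to signals, were also higher in Brown Norway than in Fisher, 8 of 19 and 0 lower, or 13 and 1 adjusted over the list alone (median 0.3, adjusted p = 0.00424; adjusted p = 0.954 with an estimated correlation). They were led by Zfp36 at 0.76 and Jund at 0.64, and the mean over the ages joins medians of 0.86, 0.02 and 0.04 at PN1, PN7 and PN14. Glucocorticoid response genes had 11 of 18 higher and 3 lower, or 11 and 4 adjusted over the list alone (median 0.45, adjusted p = 0.0136; adjusted p = 0.954 with an estimated correlation). The circadian and glucocorticoid-induced gene Per1 was 1.25 higher, Klf15 0.82 and Ddit4 0.73. At these ages the medians of the glucocorticoid list were 1.1, -0.04 and 0.13.

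Leukocyte lists gave a mixed picture in Brown Norway against Fisher. Neutrophil genes had 6 of 11 higher and 1 lower, or 9 and 1 adjusted over the list alone (median 0.22, adjusted p = 0.012; adjusted p = 0.954 with an estimated correlation). Lcn2, an iron-chelating protein also made by epithelium, was 2.93 higher, Ngp 0.82 and S100a8 0.72, while Cd177 was lower at -0.66. Mast cell genes had 7 of 10 higher and 1 lower, or 8 and 1 adjusted over the list alone (median 0.13, adjusted p = 0.0136; adjusted p = 0.954 with an estimated correlation). The chymase gene Cma1 was 0.49 higher and Gata2 0.44 higher, against the lower Kit. Interferon response genes were lower, with 12 of 23 lower and 4 higher, or 14 and 4 adjusted over the list alone (median -0.07, adjusted p = 0.00299; adjusted p = 0.954 with an estimated correlation). Ifi27 stood at -0.91, and Ifitm1 was higher at 0.51. Against Lewis the neutrophil, mast cell and interferon lists did not pass limma's camera test (adjusted p = 0.263, 0.535 and 0.962). The 12 T cell genes had 0 members past the threshold in limma (adjusted p = 0.944 for the list). Their mean stood at 9.71 on Fisher PN1 replicate 2 and at 9.37 on Brown Norway PN1 replicate 2. These arrays also had the highest thymus means (9.43 and 9.06). The SD of the T cell mean was 0.72 in Fisher PN1 and 0.5 in Brown Norway PN1, which limits what the absence of calls can show.

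The elastic fibre and collagen list was lower in Brown Norway than in Fisher, while the 20 proteoglycan genes did not pass (adjusted p = 0.993). Of 29 elastic fibre and collagen genes 11 were lower and 1 higher, or 13 and 1 adjusted over the list alone (median -0.17, adjusted p = 0.012; adjusted p = 0.954 with an estimated correlation). Col15a1 stood at -1.19 and Sparc at -0.73, while the fibrillar collagen gene Col3a1 was higher at 1.25. Against Lewis the elastic fibre and collagen list did not pass limma's camera test (median 0, adjusted p = 0.962). Averaged over the ages, cell cycle genes had 16 of 39 lower and 0 higher, or 18 and 0 adjusted over the list alone (median -0.15, adjusted p = 0.0136; adjusted p = 0.963 with an estimated correlation). This mean joins a median of -1.38 at PN1 with 0.89 at PN7 and 0 at PN14. Heart genes, which a lung sample can carry over, did not pass as a list (median 0.45, adjusted p = 0.277 against Fisher; median 0.77, adjusted p = 0.137 against Lewis). Against Lewis the atrial peptide gene Nppa was 1.97 higher and Tnnt2 1.25 higher. The mean of the heart list was 10.78 ± 1.25 (SD, n = 5) in Brown Norway PN1, 10.65 ± 1.17 (n = 4) in Fisher PN1 and 9.24 ± 0.49 (n = 3) in Lewis PN1.

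The type 2 immune, asthma susceptibility and airway contraction lists, closest to the question of the series, did not pass between any pair of strains averaged over the ages. Only 16 of 33, 14 of 42 and 13 of 35 listed genes were measured, so these results do not cover the other members. Of 16 type 2 immune response genes, Il9r and Il4r were higher in Brown Norway than in Fisher by 0.15 and 0.14, and Stat6 and Arg1 lower at -0.51 and -0.18 (adjusted p = 0.944 for the list, whose test pointed up while its median was -0.01 and its mean -0.03). Against Lewis, Arg1 and Il9r were 0.24 and 0.21 higher and the lectin gene Itln1 lower at -0.36 (adjusted p = 0.842, with the test up, a median of -0.02 and a mean of -0.04). Il4 and Il13, the central type 2 cytokines, were detected on 0 arrays. Of 14 human asthma susceptibility genes, Nod1, Il6r and Pde4d were higher in Brown Norway than in Fisher by 0.33, 0.19 and 0.09 (adjusted p = 0.277). Against Lewis, Zpbp2 and Pde4d were 0.22 and 0.1 higher and Gstm1, a glutathione transferase, lower at -0.58 (adjusted p = 0.292). At PN1 alone, tested after seeing the data, 8 of the 14 were higher than in Lewis and 1 lower, with the same counts adjusted over the list alone (median 0.09, adjusted p = 0.0345; adjusted p = 0.169 with an estimated correlation), and the list did not pass without the 2 arrays that resembled each other's group (adjusted p = 0.0574). Among 13 airway contraction receptors, the muscarinic receptor gene Chrm3 was higher in Brown Norway by 0.13 against Fisher and by 0.31 against Lewis (adjusted p = 0.993 and 0.995 for the list). The alarmin gene Il33 did not pass in any strain contrast averaged over the ages, at -0.18 (adjusted p = 0.226), -0.21 (adjusted p = 0.17) and 0.03 for Lewis minus Fisher (adjusted p = 0.912). For Brown Norway minus Lewis it passed with slide as a block (-0.32, adjusted p = 0.0151), while median scaling gave -0.02 (adjusted p = 0.928). Without the array labelled Brown Norway PN1 replicate 5 it passed against Lewis (-0.27, adjusted p = 0.0246) and Fisher (-0.24, adjusted p = 0.0389).

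Several of the largest differences between Lewis and Fisher lungs were in genes whose probe read near background in 1 of the strains. Mrpl18, a mitochondrial ribosomal protein gene, was 18-fold lower in Lewis (log2 -4.17, SE 0.05, adjusted p = 4.32e-31; -6.21 in the deposited values) and Rpl30 24-fold lower (log2 -4.58, SE 0.16). Rpl30 encodes a protein of every cytoplasmic ribosome, yet its probe read 8.66 ± 0.65 (SD, n = 3) in Lewis PN1 against 13.64 in Fisher PN1 and 13.75 in Brown Norway PN1. A sequence difference under a probe also lowers its signal, and the strains' sequences under these probes were not compared here. The WASH complex gene Washc3 and the chromatin gene Hmgn1 were 10.5-fold and 8.75-fold higher in Lewis. Lcn2 was 8.06-fold higher in Lewis (SE 0.24, adjusted p = 2.65e-11), and Scgb3a2, a secretoglobin of airway epithelium, 4.15-fold higher (SE 0.1, adjusted p = 1.64e-16). Lgals5, a galectin of red cell precursors, Cd2bp2, Qrfpr and the transporter gene Slco1a5 were 6.62-fold, 5.63-fold, 4.55-fold and 4.32-fold higher. Plekhf2, the mitophagy gene Bnip3, Zcchc9, Bcas2, Farp1 and Mfhas1 were 6.91-fold, 6.03-fold, 4.34-fold, 3.44-fold, 3.16-fold and 2.8-fold lower in Lewis. The folds of the dimmest probes depend on the background correction: in the deposited log2 values Washc3, Qrfpr, Slco1a5 and Plekhf2 stood at 4.77, 4.02, 3.11 and -5.18. In all, 1911 probes differed, 924 higher and 987 lower in Lewis, and 76 at least 2-fold. Median scaling gave 1516 (345 higher, 1171 lower), and slide as a block 2007.

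The club cell and alveolar type I lists were higher in Lewis than in Fisher, while the surfactant list (adjusted p = 0.0507) and the ciliated airway list (adjusted p = 0.614) did not pass. In all 5 of 33 lists passed, of which 0 passed limma's camera test with an estimated correlation (2 at an unadjusted p under 0.05). With median scaling class II presentation did not pass (median 0.03, adjusted p = 0.112), and the other 4 did. Club cell genes had 3 of 9 higher and 0 lower, or 4 and 0 adjusted over the list alone (median 0.22, adjusted p = 0.0154; adjusted p = 0.563 with an estimated correlation), with Cyp4b1 and Aldh1a1 each 0.57 higher beside Scgb3a2. Alveolar type I genes had 6 of 15 higher and 0 lower, or 9 and 1 adjusted over the list alone (median 0.18, adjusted p = 0.0381; adjusted p = 0.897 with an estimated correlation), led by the water channel gene Aqp5 at 0.85 and Col4a3 at 0.55. Class II presentation genes had 3 of 6 higher and 0 lower, or 5 and 0 adjusted over the list alone (adjusted p = 0.0295; adjusted p = 0.394 with an estimated correlation), among them the invariant chain gene Cd74 at 0.35. The gap was widest at PN1, where the class II mean was 10.82 in Lewis and 10.36 in Fisher. It was 10.57 and 10.48 at PN7, and 10.77 and 10.7 at PN14. Interferon response genes were lower in Lewis, 12 of 23 lower and 1 higher, or 16 and 1 adjusted over the list alone (median -0.12, adjusted p = 2.23e-06; adjusted p = 0.553 with an estimated correlation). Ifi27 stood at -0.85, Ifi44 at -0.81 and Mx2 at -0.52, with Ifitm1 higher at 0.69. Elastic fibre and collagen genes had 13 of 29 lower and 0 higher, or 15 and 1 adjusted over the list alone (median -0.22, adjusted p = 0.00402; adjusted p = 0.897 with an estimated correlation), among them Col15a1 at -0.96 and Fbn2 at -0.56. Type 2 genes did not pass as a list (adjusted p = 0.884), though Stat6 and Arg1 were lower at -0.49 and -0.42 and the eotaxin gene Ccl11 0.38 higher. The asthma susceptibility list and the airway contraction list each had an adjusted p of 0.983, and Gstm1 was 0.67 higher in Lewis. The mean of the skeletal muscle list, a tissue that can be carried over, was 9.44 ± 2.02 (SD, n = 4) in Lewis PN14 and between 8.41 and 9.01 in the other groups.

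Strain differences were also tested at each age. Between Brown Norway and Fisher, 3790 probes differed at PN1 (1753 higher, 2037 lower), 1866 at PN7 (1008 higher, 858 lower) and 1419 at PN14 (633 higher, 786 lower). Between Brown Norway and Lewis the counts were 3511 (1508 higher, 2003 lower), 1728 (906 higher, 822 lower) and 1545 (763 higher, 782 lower). Between Lewis and Fisher they were 1162 (609 higher, 553 lower), 1134 and 1429, and at PN1 773 without Lewis PN1 replicate 1. Cavin2 in Brown Norway read 11.69 ± 0.34 (SD, n = 5), 12.07 and 12.28 at the successive ages, against 8.63, 8.81 and 9.14 in Fisher. Median scaling gave 2258 (657 higher, 1601 lower), 804 (662 of them higher) and 645 probes for Brown Norway against Fisher. Against Lewis it gave 1477 (858 higher, 619 lower), 940 (796 higher, 144 lower) and 660 (393 higher, 267 lower), and for Lewis against Fisher 711 (161 higher, 550 lower), 310 and 688. Relative to quantile normalisation it shifted the median of all probes by -0.18 for Lewis minus Fisher at PN1, 0.16 and 0.13 for Brown Norway minus Lewis and minus Fisher at PN7, -0.12 for PN7 minus PN1 and 0.17 for PN14 minus PN7.

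From PN1 to PN7 red cell genes, which a lung sample can carry over with blood, rose. Fech and Alas2, enzymes of haem synthesis, rose 2.73-fold (log2 1.45, SE 0.19, adjusted p = 2.00e-06) and 2.47-fold, the erythroid regulator gene Hemgn 2.67-fold, Ahsp, which stabilises free alpha globin, 2.43-fold and Bpgm 2.39-fold. Erythroid and blood genes had 12 of 15 members higher and 0 lower, with the same counts adjusted over the list alone (median 0.39, adjusted p = 2.49e-07; adjusted p = 0.459 with an estimated correlation). The arachidonate lipoxygenase gene Alox15 rose 7.6-fold (log2 2.93, SE 0.33, adjusted p = 2.78e-07), Lgals5 4.24-fold, Tent5c 3.14-fold, Lrrn3 2.66-fold and the nucleotide-sugar receptor gene P2ry14 2.56-fold. The fetal growth factor gene Igf2 fell 2.38-fold (log2 -1.25, SE 0.31, adjusted p = 0.00299), Cdh22 3.37-fold, the defensin gene Defa5 3.14-fold, Wfdc21 2.97-fold, Gadd45g 2.34-fold, Anxa8 2.11-fold and Klf6 1.86-fold. On the log2 scale Ccn3 and Atp1b1 fell by 0.96 each and Pla2g1b fell by 0.95. Hbb read 16.02 or above in all 9 groups, near the top of the measured range, and did not pass (log2 0.02, adjusted p = 0.465).

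Matrix and vessel genes also rose between PN1 and PN7, while surfactant genes fell as a mean over the strains. Of 29 elastic fibre and collagen genes 19 rose and 1 fell, or 20 and 2 adjusted over the list alone (median 0.27, adjusted p = 4.25e-05; adjusted p = 0.459 with an estimated correlation), among them Col15a1 at 1.25, Loxl2 at 0.76 and Fbln5, needed for elastic fibre assembly, at 0.66. Of 18 endothelial genes 13 rose and 1 fell, with the same counts adjusted over the list alone (median 0.32, adjusted p = 0.000211; adjusted p = 0.459 with an estimated correlation), including the capillary gene Car4 at 0.59. Surfactant and alveolar type II genes had 9 of 13 lower and 1 higher, or 10 and 1 adjusted over the list alone (median -0.29, adjusted p = 0.00462; adjusted p = 0.459 with an estimated correlation). Lgi3 stood at -0.5, Napsa at -0.44 and Sftpc, the surfactant protein C gene, at -0.32, while the desaturase gene Scd rose by 0.57. The mean of the surfactant list was 12.08 at PN1 and 11.81 at PN7 in Lewis and 12.12 and 11.64 in Brown Norway, but in Fisher it went the other way, from 11.71 ± 0.19 to 11.83 ± 0.05 (SD, n = 4 each). Ciliated airway genes had 5 of 12 lower and 0 higher, with the same counts adjusted over the list alone (median -0.14, adjusted p = 0.0233; adjusted p = 0.601 with an estimated correlation). Xenobiotic and glutathione genes had 17 of 37 lower and 4 higher, or 19 and 4 adjusted over the list alone (median -0.13, adjusted p = 0.00426; adjusted p = 0.459 with an estimated correlation). Heart genes were lower as a list, 3 of 13 members lower and 0 higher, or 2 and 0 adjusted over the list alone (median -0.77, adjusted p = 0.0233; adjusted p = 0.65 with an estimated correlation), led by Nppa at -1.96. The heart mean went from 10.65 to 9.29 in Fisher and from 10.78 to 9.66 in Brown Norway, but in Lewis from 9.24 ± 0.49 (SD, n = 3) to 9.44 ± 0.43 (SD, n = 4).

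Between PN1 and PN7, 3754 probes changed, 1949 up and 1805 down, and 47 at least 2-fold. Median scaling gave 2871, of which 349 rose and 2522 fell. With slide as a block 3 probes passed limma's test, and 0 of the 20 named genes were among them, although all 20 kept their direction. With the block and without the 2 arrays that resembled each other's group, 560 probes passed, 13 of the 20 named genes among them, though not Fech, Hemgn, Alas2 or Ahsp (adjusted p = 0.194, 0.185, 0.0761 and 0.412), and 5 of the 7 lists, though not the erythroid and surfactant lists (adjusted p = 0.0591 each). Of the 7 lists, 0 passed limma's camera test with an estimated correlation (2 at an unadjusted p under 0.05), the heart list did not pass with median scaling (adjusted p = 0.192), and 1 passed with the slide block, the erythroid one (median 0.23, adjusted p = 1.19e-05). Sftpc turned to 0.02 with the block (adjusted p = 0.987). The blocked medians were 0.08 for elastic fibre and collagen genes, 0.1 for endothelial, -0.1 for surfactant, -0.12 for ciliated, -0.13 for xenobiotic and -0.36 for heart genes. On the slide that held Lewis PN1 and 1 Lewis PN7 array, 132 probes differed, and of the 4385 probes called from the other arrays 76.2% had the same sign. All 20 named genes had the same direction there, 2 of them past the threshold, but they were chosen with that array included and rest on that single array. The within-slide medians were 0.06 for erythroid, 0.22 for elastic fibre, 0.31 for endothelial, -0.23 for surfactant, -0.24 for ciliated, 0 for xenobiotic and -0.07 for heart genes.

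From PN7 to PN14 genes of cell division fell. Of 39 cell cycle genes 38 fell and 0 rose, with the same counts adjusted over the list alone (median -0.81, adjusted p = 6.50e-30; adjusted p = 0.058 with an estimated correlation). Rrm2, which supplies deoxynucleotides, fell 3.71-fold (log2 -1.89, SE 0.17, adjusted p = 4.99e-10), the mitotic kinase gene Cdk1 3.18-fold, Ccnb2 and Ube2c 3.09-fold each, Ccna2 2.97-fold and Knstrn 3.28-fold. Crabp1, a retinoic acid carrier, fell 3.52-fold and Unc5c 2.93-fold. Red cell genes fell as well, with 12 of 15 members lower and 0 higher, and the same counts adjusted over the list alone (median -0.62, adjusted p = 1.03e-05; adjusted p = 0.394 with an estimated correlation). Ahsp fell 3.53-fold and Hemgn 2.85-fold.

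The xenobiotic, alveolar type I, surfactant and glucocorticoid lists were higher at PN14 than at PN7, while the club, ciliated and endothelial lists did not pass (adjusted p = 0.111, 0.0725 and 0.154). The vascular amine oxidase gene Aoc3 rose 3.89-fold (log2 1.96, SE 0.17, adjusted p = 4.34e-10), the lung monooxygenase genes Fmo2 and Fmo1 3.37-fold and 2.67-fold, Apoe 2.99-fold and Mgp, an inhibitor of calcification, 2.81-fold. Adap2, Cyp2e1, Gsn, Klf9 and Sec14l3 rose 2.76-fold, 2.64-fold, 2.52-fold, 2.49-fold and 2.48-fold. Xenobiotic and glutathione genes had 21 of 37 higher and 5 lower, or 23 and 5 adjusted over the list alone (median 0.17, adjusted p = 4.32e-05; adjusted p = 0.108 with an estimated correlation). Alveolar type I genes had 10 of 15 higher and 0 lower, with the same counts adjusted over the list alone (median 0.36, adjusted p = 0.000541; adjusted p = 0.285 with an estimated correlation), led by Aqp5 at 1.16 and Clic5 at 0.63. Surfactant genes had 7 of 13 higher and 0 lower, with the same counts adjusted over the list alone (median 0.27, adjusted p = 0.00407; adjusted p = 0.484 with an estimated correlation), among them Scd at 0.73 and Sftpa1 at 0.63. Glucocorticoid response genes had 11 of 18 higher and 2 lower, or 13 and 2 adjusted over the list alone (median 0.27, adjusted p = 0.00121; adjusted p = 0.422 with an estimated correlation), including Klf9 at 1.32 and Tsc22d3 at 1.12.

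Of the immune lists, the interferon, class I, class II, B cell and NK lists were higher at PN14 than at PN7. The T cell, macrophage, mast cell, neutrophil and eosinophil lists did not pass (adjusted p = 0.13, 0.132, 0.176, 0.977 and 0.648). Interferon response genes had 15 of 23 higher and 1 lower, or 16 and 1 adjusted over the list alone (median 0.18, adjusted p = 1.03e-05; adjusted p = 0.285 with an estimated correlation), among them Psmb8 at 0.61 and Ifitm3 at 0.46. Class I presentation genes had 10 of 16 higher and 0 lower, or 11 and 1 adjusted over the list alone (median 0.18, adjusted p = 0.000264; adjusted p = 0.484 with an estimated correlation). Class II presentation genes had 5 of 6 higher and 0 lower, with the same counts adjusted over the list alone (median 0.27, adjusted p = 0.00895; adjusted p = 0.108 with an estimated correlation), including Cd74 at 0.51. B cell genes had 6 of 7 higher and 0 lower, also adjusted over the list alone (median 0.24, adjusted p = 0.00668; adjusted p = 0.484 with an estimated correlation), with Cd37 at 0.48 and Cd79b at 0.35. NK and cytotoxic genes had 6 of 8 higher and 0 lower, also adjusted over the list alone (median 0.09, adjusted p = 0.0241; adjusted p = 0.484 with an estimated correlation), with the perforin gene Prf1 at 0.29. The NK mean went from 8.44 to 8.7 in Lewis and from 8.46 to 8.64 in Fisher, but in Brown Norway from 8.58 ± 0.15 to 8.51 ± 0.16 (SD, n = 4 each), where the array labelled PN14 replicate 3 read 8.34. The NK list did not pass with median scaling (adjusted p = 0.139) or in the deposited values (adjusted p = 0.052). The T cell list passed in the deposited values (adjusted p = 0.0171) and without background correction (adjusted p = 0.0353). Human asthma susceptibility genes had 6 of 14 higher and 0 lower, or 8 and 0 adjusted over the list alone (median 0.16, adjusted p = 0.00634; adjusted p = 0.058 with an estimated correlation). Among them Il33 rose by 0.71 (SE 0.11, adjusted p = 7.08e-06), after 0.47 between PN1 and PN7 (adjusted p = 0.002), and Ormdl3 and Il6r rose by 0.43 each. Neither step of Il33 passed with slide as a block (0.39, adjusted p = 0.29, and 0.1, adjusted p = 0.947), and with median scaling the first did not (0.3, adjusted p = 0.116). Type 2 genes did not pass as a list (adjusted p = 0.432), with Retnla and Alox15 lower at -0.97 and -0.88 and Ccl11 0.6 higher.

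Between PN7 and PN14, 5187 probes changed, 2503 up and 2684 down, and 99 at least 2-fold, and between PN1 and PN14 5966 changed, 2884 up and 3082 down. Median scaling gave 5213 (4585 up, 628 down) and 4035 (2575 up, 1460 down). With slide as a block 819 and 256 probes passed, and 13 of the 20 genes named for PN7 to PN14 were past the threshold, all 20 in the same direction. Of the 12 lists, 0 passed limma's camera test with an estimated correlation (5 at an unadjusted p under 0.05), and 10 passed with the slide block. With the block and without the 2 arrays that resembled each other's group, 822 probes, 18 of the 20 named genes and 8 of the 12 lists passed. The medians with the block alone were -0.76 for cell cycle, -0.36 for erythroid, 0.49 for surfactant, 0.34 for alveolar type I, 0.67 for glucocorticoid, 0.11 for xenobiotic, 0.08 for interferon, 0.28 for class II, 0.1 for asthma and 0.2 for B cell genes. Class I presentation (median 0.05, adjusted p = 0.353) and NK genes (median 0.04, adjusted p = 0.314) did not pass with it, and Scd turned to -0.1 (adjusted p = 0.932). On the slide that held Lewis PN7 and 1 Lewis PN14 array, 1081 probes differed, 93.7% of the 5136 probes called from the other arrays had the same sign, and all 20 named genes had the same direction, 18 past the threshold, again with 1 array on the PN14 side that had entered the choice of the genes. There all 39 cell cycle genes were lower (median -0.82) and all 15 erythroid genes lower (median -0.56). The other medians on that slide were 0.41 for surfactant, 0.32 for alveolar type I, 0.39 for glucocorticoid, 0.14 for xenobiotic, 0.16 for interferon, 0.3 for class I, 0.2 for class II, 0.15 for asthma, 0.35 for B cell and 0.2 for NK genes. Another slide held Brown Norway PN14 and the array labelled Brown Norway PN1 replicate 5. There 45.6% of 6261 probes called from the other arrays had the same sign. This cannot test age, as that array resembled PN14 and PN14 replicate 3 resembled PN1.

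**Figure D3:**
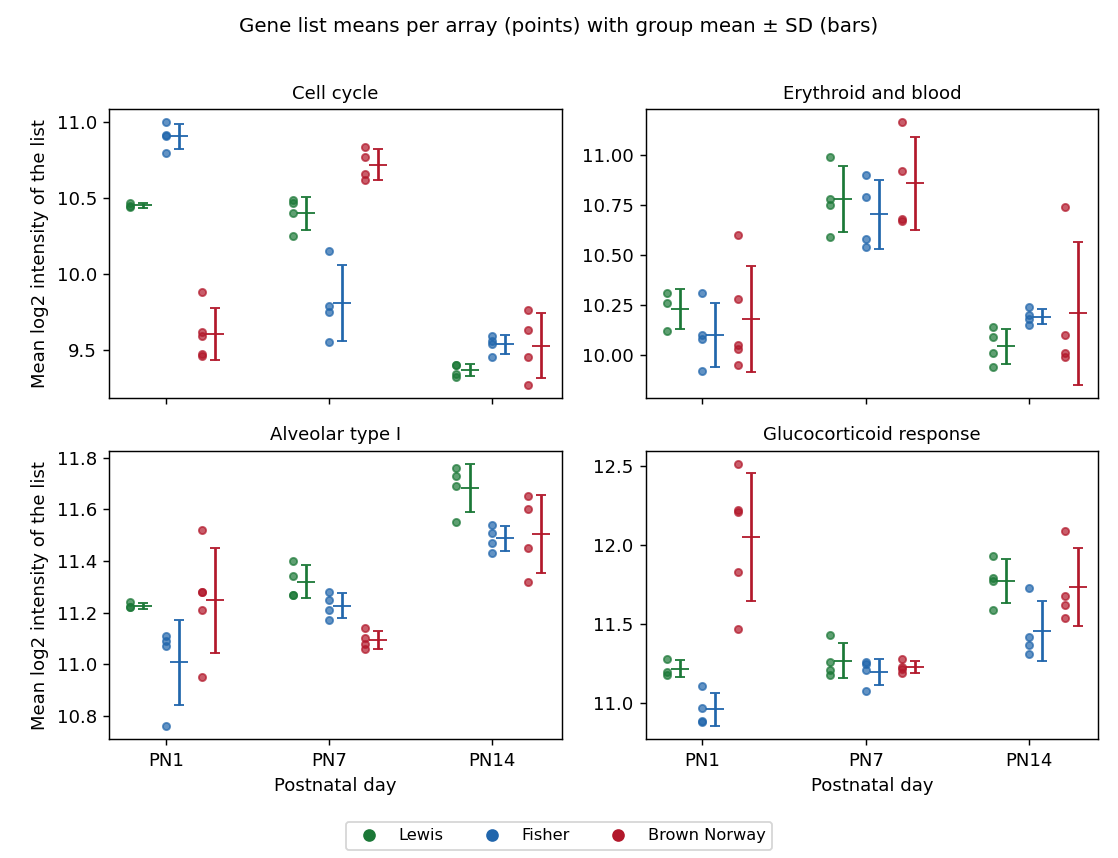
Mean log2 intensity of 4 gene lists (y axis) by postnatal day (x axis), with a point per array and bars for the group mean ± SD of 3 to 5 arrays. Cell cycle genes average 9.6 in Brown Norway, 10.46 in Lewis and 10.91 in Fisher at PN1, and 10.72, 10.4 and 9.81 at PN7.

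The strains did not follow the same course with age. The 10 smallest p-values of the strain by age term belonged to Iqgap3, Mxd3, Cenpt, Pbk, Bub1b, Fbxo5, Ect2, Racgap1, Kif15 and Mki67, with adjusted p from 8.97e-15 for Iqgap3 to 5.14e-13 for Mki67. Pbk, a mitotic kinase, read 10.67 ± 0.14 (SD, n = 4) in Fisher and 8.53 ± 0.24 (n = 5) in Brown Norway at PN1, and 8.96 ± 0.33 and 10.31 ± 0.16 (n = 4 each) at PN7. Lewis lay between both at 10.1 and 9.82. At PN14 the values were 8.63, 8.56 and 8.45 in Fisher, Brown Norway and Lewis. Mki67, the marker of cycling cells, read 9.13 in Fisher and 8.32 in Brown Norway at PN1, and 8.4 and 8.82 at PN7. Rrm2, Ccna2, Crabp1, Klf9 and Aoc3, named above for age, also had a strain by age term (adjusted p from 6.42e-12 for Ccna2 to 0.00015 for Aoc3).

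Gene lists were tested at each age after these values had been seen. In Brown Norway against Fisher 38 of 39 cell cycle genes were lower at PN1, also adjusted over the list alone (median -1.38, adjusted p = 4.19e-37; adjusted p = 0.0452 with an estimated correlation). At PN7 37 were higher, also adjusted over the list alone (median 0.89, adjusted p = 1.19e-41; adjusted p = 0.0258 with an estimated correlation), and at PN14 the list did not pass (median 0, adjusted p = 0.941). Against Lewis 37 were lower at PN1, also adjusted over the list alone (median -0.8, adjusted p = 2.26e-22; adjusted p = 0.169 with an estimated correlation) and 18 higher at PN7, or 21 adjusted over the list alone (median 0.31, adjusted p = 2.99e-10; adjusted p = 0.937 with an estimated correlation). In the deposited values 3 were higher at PN7 (median 0.4). Glucocorticoid response genes were higher in Brown Norway at PN1, 12 of 18 against Fisher, also adjusted over the list alone (median 1.1, adjusted p = 4.52e-06; adjusted p = 0.292 with an estimated correlation) and 10 higher and 0 lower against Lewis, or 10 and 1 adjusted over the list alone (median 0.66, adjusted p = 0.000182; adjusted p = 0.57 with an estimated correlation). Immediate early genes were higher at the same age, 13 of 19 against Fisher, or 16 adjusted over the list alone (median 0.86, adjusted p = 4.52e-06; adjusted p = 0.536 with an estimated correlation), and 9 higher and 1 lower against Lewis, or 12 and 1 adjusted over the list alone (median 0.57, adjusted p = 0.00275; adjusted p = 0.676 with an estimated correlation). Against Fisher at PN7 and PN14, glucocorticoid genes did not pass (adjusted p = 0.607 and 0.624), nor did immediate early genes, with 1 higher at each age (adjusted p = 0.772 and 0.685). Heart genes were higher in Brown Norway than in Lewis at PN1, 4 of 13, or 11 adjusted over the list alone (median 1.61, adjusted p = 0.00486; adjusted p = 0.755 with an estimated correlation) and not against Fisher (median 0.02, adjusted p = 0.737).

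A strain by age term was found for 2517 probes, 22.2% of those tested, and for 4150 without the 2 arrays that resembled each other's group. The change from PN1 to PN14 differed for 513 probes between Brown Norway and Fisher (369 higher, 144 lower), for 1150 between Brown Norway and Lewis (753 higher, 397 lower) and for 366 between Lewis and Fisher (159 higher, 207 lower). Without those arrays the counts were 1586, 2402 and 694. Median scaling gave 745 for the term and 250 (227 higher, 23 lower), 188 and 91 (74 higher, 17 lower) for the changes. The Lewis and Fisher count was 217 without Lewis PN1 replicate 1 and 241 without Lewis PN1 replicate 3.

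Genes of interest fixed in advance showed modest differences. Eln, which encodes elastin, rose by 0.47 (SE 0.17, adjusted p = 0.0376) and then by 0.71 (adjusted p = 0.00135) over both steps in age and did not pass between strains (adjusted p = 0.56, 0.649 and 0.377), though without the 2 arrays that resembled each other's group it was lower in Lewis than in Fisher (adjusted p = 0.023). Col1a1 rose by 0.36 and 0.51, and was lower in Brown Norway and in Lewis than in Fisher at -0.37 (adjusted p = 0.0288) and -0.42 (adjusted p = 0.0327). Neither step in age passed with slide as a block for Eln (0.08 and 0.45, adjusted p = 0.979 and 0.526) or for Col1a1 (0.04 and 0.04, adjusted p = 0.988 and 0.954). With the block and without those 2 arrays, both steps passed for Eln (0.87 and 1.39, adjusted p = 0.0108 and 0.000111), and the second did for Col1a1 (0.6, adjusted p = 0.0237) while the first did not (0.48, adjusted p = 0.0856). In that setting Eln also passed for Brown Norway minus Lewis (0.24, adjusted p = 0.0211) and Lewis minus Fisher (-0.34, adjusted p = 0.00187). With median scaling the first step did not pass for Eln or Col1a1 (adjusted p = 0.116 and 0.208), nor did Col1a1 for Brown Norway minus Fisher (adjusted p = 0.0673). Dcn, a proteoglycan that binds collagen, was lower than in Fisher at -0.97 in Brown Norway (adjusted p = 4.57e-05) and -0.58 in Lewis (adjusted p = 0.0208). Its age differences of 0.41 and 0.22 did not pass (adjusted p = 0.0693 and 0.318), and the second turned to -0.46 with the block (adjusted p = 0.498) and to -0.08 with the block and without those 2 arrays (adjusted p = 0.924). Sftpc, after its fall to PN7, rose by 0.32 to PN14 (adjusted p = 9.47e-05), and was lower in Brown Norway than in Lewis at -0.18 (adjusted p = 0.0338), a sign that turned with median scaling. Neither of these passed with the block (adjusted p = 0.0538 and 0.101). Scgb1a1, the club cell secretory protein gene, read between 15.98 and 16.06 in all groups, near the top of the range, where differences can be understated. Its difference of 0.04 from PN7 to PN14 lay at the threshold (adjusted p = 0.0487). It did not pass without background correction, in the deposited values or with slide as a block (adjusted p = 0.164, 0.23 and 0.815). With single arrays left out its adjusted p ran from 0.0212, without the array labelled Brown Norway PN1 replicate 5, to 0.108, without Fisher PN7 replicate 4. Its strain differences of -0.01, -0.03 and 0.02, for Brown Norway minus Fisher, Brown Norway minus Lewis and Lewis minus Fisher, did not pass (adjusted p = 0.699, 0.192 and 0.514), nor did those of Hbb (0.03, 0.03 and 0; adjusted p = 0.169, 0.189 and 0.993). Median scaling gave 0.33 for Hbb in Brown Norway minus Lewis (adjusted p = 0.00182), and turned the sign of Scgb1a1 in Brown Norway minus Lewis (0.28, adjusted p = 0.00324) and Lewis minus Fisher (-0.2, adjusted p = 0.0495). For Scgb1a1 in Brown Norway minus Lewis, slide as a block gave -0.04 (adjusted p = 0.0374), and leaving out the array labelled Brown Norway PN1 replicate 5 gave -0.04 (adjusted p = 0.0418). Averaged over the ages, Mki67 was lower in Brown Norway than in Fisher at -0.13 (adjusted p = 0.000438). As a mean over the strains it fell by 0.13 and then by 0.29 over both steps in age. The first of these did not pass with slide as a block (adjusted p = 0.499) or in the deposited values (adjusted p = 0.228). These means hide opposite courses, since from PN1 to PN7 Mki67 rose in Brown Norway and fell in Fisher. It was lower in Brown Norway than in Fisher at PN1 and higher at PN7. Acta2 and Myh11 had no named probe.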

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

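The tests of the 2 Brown Norway arrays that lie away from their groups, the settings without them, the test of slide on the cell cycle genes with its criterion and the test with reordered residuals were chosen after the result was seen. In the first of those tests the criterion for the strain scale was also changed after its value was seen, from over 0.75 to the range of the other Brown Norway arrays. On that scale, from the other strains (0) to Brown Norway (1) over 4471 probes, replicate 5 stood at 0.67, beside 0.62 to 0.69 for the other Brown Norway PN14 arrays, and replicate 3 at 1.1, beside 0.96 to 1.26 for the other PN1 arrays.

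The arrays labelled Brown Norway PN1 replicate 5 and Brown Norway PN14 replicate 3 lay away from their groups. On a scale over 5845 probes from the other Brown Norway PN1 arrays (0) to the other PN14 arrays (1), replicate 5 stood at 0.93 and replicate 3 at 0.12, so that the lesser displacement was 0.88, and an exchange of the labels of these arrays is a candidate explanation. A slide effect is argued against for both, as replicate 3 shared the slide of replicate 5 and stood at 0.12. Lewis arrays on another age's slide stayed at 0.16 and 0.1 of the way to its age. For tissue carried over from heart, muscle or fat, 1 of 6 list means of these arrays lay outside the range of the other Brown Norway arrays. That range was wide, with heart means up to 12.82. The mean outside it was adipose on replicate 5, at 10.2, so such tissue stays open for that array. For replicate 3 it is argued against. Its heart, skeletal muscle and adipose means (10, 8.67 and 8.71) did not exceed the highest in Brown Norway PN14 (10.45, 8.91 and 10.07). An animal of unusual maturity was not tested and stays open.

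Strain differences were set against slide position. Both Lewis arrays outside the Lewis sections stayed with Lewis, the higher at 0.06 from Lewis (0) to Brown Norway (1). This argues against those sections as the cause for these strains. No array lay in another strain's sections, so position otherwise stays open. Among the 45 probes over 2-fold apart in Brown Norway, 68.9% were higher there (95% exact binomial interval 53.4 to 81.8), which could come from sequence variants, since Brown Norway is the strain of the reference genome. Between Lewis and Fisher the share that was higher in Lewis also grew with the fold, to 61.8% over 2-fold (Fisher's exact p = 0.556), so variants and regulation cannot be told apart for these probes. Inherited differences in regulation stay open.

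Age differences were set against the slide, since 3 arrays carry an age onto another age's slide. On the scale from its own age (0) to that of its slide (1), the Lewis PN7 array on the PN1 slide stood at 0.16, beside 0.08 to 0.3 for the other Lewis PN7 arrays, and the Lewis PN14 array on the PN7 slide at 0.1, beside 0.01 to 0.1. For the fall of cell cycle genes from PN7 to PN14, slide as the whole cause is argued against, because the median with slide as a block was -0.76, against -0.81 without it, with 34 of 39 genes past the threshold, and 10 of the 12 lists that passed for this step did so with the block. For the age differences as a whole slide and age cannot be told apart, because each step has a single Lewis array on another age's slide and the third such array, labelled Brown Norway PN1 replicate 5, stood at 0.93 but has a doubtful label, while 560 probes passed for PN7 minus PN1 with the block and without the 2 doubtful arrays. Development itself stays open.

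Within groups of 4 or 5 arrays, 9 of 80 tests of a list mean or array measure found an array far from the others, where chance gives about 1 in 20. The erythroid mean was 10.74 on the array labelled Brown Norway PN14 replicate 3 (nearest 10.1). The thymus mean was 9.43 on Fisher PN1 replicate 2 (nearest 8.544) and 9.06 on Brown Norway PN1 replicate 2 (nearest 8.573). The skeletal muscle mean was 12.46 on Lewis PN14 replicate 2 (nearest 8.626) and 9.33 on Fisher PN14 replicate 2 (nearest 8.458). The adipose mean was 10.2 on the array labelled Brown Norway PN1 replicate 5 (nearest 9.071) and 9.09 on Brown Norway PN7 replicate 1 (nearest 8.697). The oesophagus mean, of 2 genes, was 9.83 on Lewis PN14 replicate 2 (nearest 8.202), and the liver mean was 8.57 on Fisher PN1 replicate 2 (nearest 8.707). Of the 94 probes of named genes, an array stood apart for 24 in Brown Norway PN1 (replicate 5 in 22) and for 19 in Brown Norway PN14 (replicate 3 in 16). The numbers were 5 in Fisher PN1, 7 in Lewis PN7, 5 in Fisher PN7, 4 in Brown Norway PN7, 5 in Lewis PN14 and 6 in Fisher PN14.

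The effect of age differed between strains for 2517 probes. The genes with the smallest adjusted p were Iqgap3 (8.97e-15), Mxd3 and Cenpt (4.69e-14 each), Pbk (1.14e-13), Bub1b (2.88e-13), Fbxo5 and Ect2 (3.03e-13 each), Racgap1 (4.41e-13), and Kif15 and Mki67 (5.14e-13 each). The change from PN1 to PN14 differed for 513 probes between Brown Norway and Fisher, for 1150 between Brown Norway and Lewis and for 366 between Lewis and Fisher.

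Other divisions of the same arrays, 100 drawn or all 35 or 56 possible, were fitted for each count. Chance here means only a chance division of these arrays. The labels do not state that replicates are separate animals, so chance differences between animals are not covered. For the age contrasts the divisions cannot separate age from slide, which largely coincide. Chance can be excluded for Brown Norway against Fisher (3612, highest other division 655) and at PN1 (3790, 3752), PN7 (1866, 74) and PN14 (1419, with 7.5% of that in the highest other). The division with 3752 calls exchanged all 4 Fisher PN1 arrays with 4 of the 5 Brown Norway PN1 arrays, and so nearly mirrors the real one. It can be excluded for Brown Norway against Lewis (3157, 1730) and at PN1 (3511, 2671), PN7 (1728, 1) and PN14 (1545, 65), and for Lewis against Fisher (1911, 420) and at PN1 (1162, 560), PN7 (1134, 98) and PN14 (1429, 2). It can also be excluded for PN7 minus PN1 (3754, 571), PN14 minus PN7 (5187, 241), PN14 minus PN1 (5966, 1862) and Brown Norway apart from both (1860, 0). For the strain by age results these divisions do not measure chance, because exchanging strains at an age turns the strain difference itself into a difference in change. They gave up to 396 for the strain by age term (1 of 100 as large), 4202 for Brown Norway against Fisher (5 of 100), 1960 for Brown Norway against Lewis (6 of 100) and 500 for Lewis against Fisher (2 of 100). The division with 4202 exchanged the same PN1 arrays, and that with 1960 exchanged all 3 Lewis PN1 arrays with 3 Brown Norway PN1 arrays. With the strain and age differences kept and the residuals reordered over the arrays, 1 of 100 orders, the real one, was as large for each. The highest others were 2 for the term (2517), 4 for Brown Norway against Fisher (513), 149 for Brown Norway against Lewis (1150) and 9 for Lewis against Fisher (366), so chance can be excluded. It cannot be excluded for any count of gene lists: Brown Norway against Fisher (8, 16, 47 of 100), against Lewis (1, 16, 100 of 100), Lewis against Fisher (5, 13, 79 of 100), PN7 minus PN1 (7, 13, 35 of 100) and PN14 minus PN7 (12, 15, 12 of 100).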

How the results depend on the processing

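The settings without 2 Brown Norway arrays, with heart and adipose means as covariates and without the 3 arrays with most skeletal muscle signal, and the tests with them, were chosen after the results were seen. Slide limits the age results most and scaling the split between higher and lower, and signal near background limits the folds of dim probes. Replicate numbers did not pair the arrays, since 136 same-numbered pairs had a mean correlation of deviations of 0.007 (-0.491 to 0.441), with 37 over 0.1, against -0.002 for other pairs. Replicate number as a block moved no count by over 1.5 times (4080, 3734 and 2104 probes for the strain contrasts, 4434 and 5414 for the age steps, 3193 for the strain by age term). Of 331 named results, 330 kept direction and side of the threshold without background correction, 327 with the authors' deposited values, 298 with median scaling, 330 with a trended and robust variance, 318 with no filter and 323 without the 3 bridging arrays. With slide as a fixed block 234 did and 92 were weaker. A Y-linked covariate was not run, for want of named probes. The cause was not tested for any change below unless the setting's construction gives it.

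Without background correction 3 gene lists passed for Brown Norway minus Lewis, in place of 1. The authors' deposited values gave 2 lists there, 8 for Lewis minus Fisher in place of 5, and 208 probes in place of 366 for the difference in change between Lewis and Fisher. With no filter, with detection on at least 18 arrays and with slide as a block, 2 lists passed for Brown Norway minus Lewis.

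Median scaling gave 1850 probes for Brown Norway minus Fisher in place of 3612, and 2258, 804 and 645 at PN1, PN7 and PN14. It gave 1477, 940 and 660 at these ages for Brown Norway minus Lewis and 711, 310 and 688 for Lewis minus Fisher. Brown Norway stood apart from both for 870 probes in place of 1860, and 745 in place of 2517 had a strain by age term. The differences in change fell to 250, 188 and 91, and 12 lists passed for PN7 minus PN1 in place of 7. Sftpc reversed for Brown Norway minus Lewis (log2 0.02, adjusted p = 0.936), as did Scgb1a1 (0.28, adjusted p = 0.00324), and for Lewis minus Fisher Scgb1a1 also did (-0.2, adjusted p = 0.0495).

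With slide as a fixed block 3 probes passed for PN7 minus PN1 (2 up, 1 down) in place of 3754, 819 for PN14 minus PN7 (326 up, 493 down) in place of 5187 and 256 for PN14 minus PN1 (82 up, 174 down) in place of 5966, and 1 list passed for PN7 minus PN1. Few arrays bridge the slides, which by construction leaves less of the age contrast. The bridging array labelled Brown Norway PN1 replicate 5 stood at 0.93 on the scale from Brown Norway PN1 (0) to PN14 (1). Without the 2 doubtful Brown Norway arrays, more probes passed with the block for PN7 minus PN1 and for PN14 minus PN1, as given below. The small counts therefore depend on these arrays and their labels as well. Sftpc reversed for PN7 minus PN1 (0.02, adjusted p = 0.987) and Scd for PN14 minus PN7 (-0.1, adjusted p = 0.932). As a random block, slide gave 992, 2937 and 3064. Within a slide 132, 1081 and 0 probes passed in limma, the 0 on the slide with the array labelled Brown Norway PN1 replicate 5, where 254 had an unadjusted p under 0.05.

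Without the 2 Brown Norway arrays 4150 probes had a strain by age term, the differences in change rose to 1586, 2402 and 694, and 2 lists passed for Brown Norway minus Lewis. With the slide block as well, the age counts were 560, 822 and 860, 13 and 18 of the 20 genes named for each step passed in place of 0 and 13 with the block alone, and 5 of 7 and 8 of 12 lists in place of 1 and 10, the differences in change 1575, 2297 and 677, and the strain by age count 3960. With heart and adipose means as covariates 3976 probes passed for PN14 minus PN1 and 2 lists for Brown Norway minus Lewis, and the heart list reversed for PN7 minus PN1 (adjusted p = 0.935), as the covariate holds its own genes. Without the 3 arrays with most skeletal muscle signal 4 lists passed for Brown Norway minus Lewis.

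With an estimated correlation 0 lists passed camera in each of the 5 contrasts, and 1, 0, 2, 2 and 5 had an unadjusted p under 0.05. With the Brown Norway arrays divided between both comparisons, 1211 and 1182 probes were apart from both. Leaving out 1 array at a time, the counts ranged from 773 to 1318 for Lewis minus Fisher at PN1, lowest without Lewis PN1 replicate 1. They ranged from 217 to 480 for the difference in change between Lewis and Fisher, with 217 without Lewis PN1 replicate 1 and 241 without replicate 3. The lists for Brown Norway minus Lewis ranged from 1 to 3, with 3 without Lewis PN14 replicate 2. There were 2 without Lewis PN1 replicate 1, Brown Norway PN1 replicate 3, Lewis PN7 replicate 4, Fisher PN7 replicates 2 and 3, Brown Norway PN7 replicates 2 and 3, Lewis PN14 replicate 3 or the arrays labelled Brown Norway PN14 replicates 3 and 4.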

Other observations

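The tests of gene lists at each age were chosen after the strain by age results had been seen, as was the test of all neighbours that differ between Lewis and Fisher, and the other tests of chromosomal neighbours were not.

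Within lists that did not pass for a step in age, single members did. Smooth muscle contractile genes, 15 measured, had 5 higher and 0 lower from PN1 to PN7, with Smtn at 0.77 and Cald1 at 0.46, and 7 lower and 0 higher from PN7 to PN14, with Actg2 at -0.71 and Myl9 at -0.64, the same counts adjusted over the list alone (adjusted p = 0.0868 and 0.1 for the list), while 33.1% and 45.7% of all tested probes changed over the same steps. Regulators of alveolarisation moved both ways. From PN1 to PN7 the retinoic acid hydroxylase gene Cyp26b1 rose by 0.99 and Tgfb2 by 0.76 beside the fall of Igf2, and from PN7 to PN14 Fgfr4 rose by 0.52 and Pdgfra, the receptor of alveolar myofibroblast precursors, by 0.41 (adjusted p = 0.271 and 0.446, the latter with the test up, a median of 0.07 and a mean of -0.03). Among proteoglycans Vcan, a large proteoglycan of immature matrix, fell by 1.17 from PN7 to PN14 while Prelp rose by 1.14 (adjusted p = 0.648). The elastin microfibril gene Fbn2 fell by 1.1 over the same step while Mfap5 rose by 0.8 and Col3a1 by 0.68 (adjusted p = 0.78 for elastic fibre and collagen genes).

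Some genes differed strongly between strains within lists that did not pass. The endothelial nitric oxide synthase gene Nos3 was -1.2 in Brown Norway minus Fisher and -1.41 in Lewis minus Fisher (endothelial list, adjusted p = 0.944 and 0.956, the former with the test up, a median of -0.03 and a mean of -0.04). The proteoglycan gene Fmod was 1.42 and 1.46 higher in the same contrasts (adjusted p = 0.993 and 0.983 for proteoglycans). Tcf4, which encodes a helix-loop-helix transcription factor and stood in the Wnt list although it is not the Wnt effector Tcf7l2, was -1.2 in Brown Norway minus Lewis and 1.6 in Lewis minus Fisher (adjusted p = 0.94 and 0.956 for Wnt signalling). Clec7a, a receptor for fungal glucans on macrophages, was -1.05 in Brown Norway minus Lewis (macrophage list, adjusted p = 0.304). From PN1 to PN7 the type 2 genes Retnla and Postn rose by 1.19 and 0.26 beside Alox15 (adjusted p = 0.244 for the list). Thymus, liver, eosinophil, skeletal muscle and adipose lists passed in 0 of the 5 averaged contrasts, with their lowest adjusted p at 0.375, 0.244, 0.244, 0.203 and 0.132.

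At single ages further list differences passed. Surfactant genes were higher in Brown Norway than in Fisher at PN1, 8 of 13, also adjusted over the list alone (median 0.44, adjusted p = 0.00548; adjusted p = 0.61 with an estimated correlation). At PN14 interferon genes were lower in Brown Norway than in Fisher, 11 of 23 and 2 higher, or 13 and 2 adjusted over the list alone (median -0.09, adjusted p = 5.80e-06; adjusted p = 0.647 with an estimated correlation). Skeletal muscle genes were higher in Lewis than in Fisher at PN14, 1 of 9, or 0 adjusted over the list alone (median 1, adjusted p = 0.0245; adjusted p = 0.829 with an estimated correlation), on the group that holds the array with a muscle mean of 12.46.

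Whether genes apart in Brown Norway lie next to each other on the chromosomes was tested as a hypothesis of differences inherited with stretches of the chromosome. Of neighbouring pairs among 8052 measured genes, in the order of the GRCr8 assembly, 267 had both members apart in Brown Norway, against a median of 202 and a central 95% range of 179 to 226 in 2000 shuffled orders. In the same direction were 169 pairs, 1.66 times the shuffled median. Over 1.5-fold 6 pairs were apart in Brown Norway, against 0 to 4 when shuffled, and 3 of them went in the same direction, against 0 to 2. RT1-A2 and RT1-A1 were both higher in Brown Norway, while Ly6c (-1.6) and Ly6i (2.14), and Phf20 (-0.86) and Scand1 (0.97), went in opposite directions. Between Lewis and Fisher 324 pairs differed, against 219 to 270 when shuffled, with 178 in the same direction, 1.46 times the shuffled median, while over 1.5-fold 5 pairs and 3 in the same direction lay within the shuffled ranges of 0 to 6 and 0 to 4. Genes that changed from PN7 to PN14 formed 1815 pairs, within the shuffled range of 1770 to 1856, though their 993 pairs in the same direction exceeded the range of 857 to 954. Over 1.5-fold these numbers were 12 (4 to 16) and 10 (1 to 10). Inheritance in stretches may account for the excess of 267 pairs, but probes that read related neighbours, as in the RT1 and Ly6 families, stay open.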
